A study of Mus musculus with 6 samples.

How the data were processed

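The series holds RNA-seq libraries of BV2 microglial cells, 3 labelled as SMEK1 knockdown and 3 labelled as WT. Per the labels' protocols, cells were grown in DMEM with serum and antibiotics, RNA was extracted with a column kit, and sequencing libraries were made from 1.3 µg of total RNA with a SMARTER mRNA kit. Per the submitters' processing notes the genome build was GRCm38 (mm10). The aligner, the counting program, its use of strand and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

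The authors deposited a table of whole-number counts per gene for 54532 Ensembl mouse genes in the 6 libraries, with symbols, positions and biotypes. They also deposited FPKM values, and a table with the same FPKM values and their means per group. For each library, the deposited FPKM equalled the count divided by the gene length and by a constant of that library. This constant was 1.02 to 1.12 times the sum of counts in the knockdown libraries and 0.911 to 0.991 times in the WT libraries, so the FPKM of the authors carry a scaling between libraries of their own. Of the identifiers, 54495 are in GENCODE M21, and 53585 (98.3%) have the same start and end there.

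Library totals were 18627425 to 21131557 counts in the knockdown group and 18036591 to 18708438 in the WT group, and 21676 genes had a count in any library. The biological coefficient of variation was 0.121. Where all libraries of a group had 0 counts, folds were computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% counting interval. Reads carried no stated molecular identifiers, so these bounds describe counting error only.

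Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 12269, of which 10799 are protein-coding. Libraries were scaled by TMM, and the SMEK1 knockdown and WT groups were compared with glmQLFit and glmQLFTest without covariates. All adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested unless another tool is named, and genes were called at an adjusted p under 0.05. Fold changes are log2 of knockdown over WT, and group values are means of TMM-scaled CPM ± SD over 3 libraries. Each standard error (SE) was computed as the size of the fold change divided by the square root of the test's F statistic. These SE are approximate and can be too small where a group has few counts. Shares of counts were compared by an exact permutation test of group labels. Overlap between the groups means that the ranges of their libraries' CPM overlap.

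Gene lists were tested with camera of limma 3.58.1, which compares a list with all other genes tested, at a preset correlation between genes of 0.01. Of 56 lists the 48 with at least 5 tested members were adjusted together by Benjamini-Hochberg. Members were counted as called over all genes tested and adjusted over the list alone. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the subunits of protein phosphatase 4, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes, clone names and pseudogenes, a panel of genes of glucose, lactate, inflammation and histone acylation, and the members with the smallest adjusted p of each list that was called or had at least 5 called members. The chromosome medians were chosen after the data were seen, and use genes with a mean log2 CPM above 2 in bins of 10 Mb.

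The scripts were tested on simulated data with the means and library sizes of these libraries for the knockdown against WT comparison. Of 67 genes simulated with a 1.5-fold change 44.8% were recovered, of 67 with 2-fold 71.6% and of 66 with 4-fold 95.5%. Among 12131 genes 10 of 151 calls were false (6.62%). The other simulated genes were unchanged, while 40.1% of genes were called in the data, so these shares need not hold there. A simulated 1.5-fold fall of the glycolysis list was recovered by camera with the preset correlation, camera with an estimated correlation and fry. With each of them 0 other lists were called. The simulated genes varied independently, so this does not test the preset correlation of 0.01. In the data the estimated correlation was 0.264 for glycolysis, 0.729 for cytosolic ribosomal proteins and -0.0207 for the type I interferon response.

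The alternatives were size factors of DESeq2, upper quartile or library totals in place of TMM, other filters on low counts, DESeq2 1.42.0 and limma-voom in place of edgeR, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, protein-coding genes alone, a replicate block, a test against a fold of 1.5, a stricter adjusted p of 0.01, an estimated correlation or fry for the lists, and leaving out each library in turn. Added after the data were seen were a covariate from the residuals and the removal of chromosomes 14 and 16. Near-identical copies of Gapdh were found with blastn 2.17.0 among the transcripts of the reference, at 85% identity over at least 300 bases, the minimum set beforehand; 200 bases were used first by mistake, and both results had been seen when 300 was kept.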

Results

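RNA was sequenced from BV2 cells, a mouse microglial cell line, in 2 groups of 3 libraries each. In the knockdown group the target was SMEK1, a regulatory subunit of protein phosphatase 4, whose gene is listed as Ppp4r3a. The sample labels call the other group WT, while the design text of the series counts both groups as knockdown derivatives of BV2. Whether the WT cells received a control construct is not given in the sources used here. The title of the series concerns SMEK1, lactylation of histone H3 and ischaemia-reperfusion injury. The comparison asks how the transcripts of the knockdown libraries differ from those of the WT libraries, with no labelled stimulus. Library totals were 18627425, 20594145 and 21131557 counts for knockdown A, B and C, and 18708438, 18482282 and 18036591 for WT A, B and C. At these depths 1 count stood for 0.0444 to 0.0597 counts-per-million (CPM). Pearson correlations across genes, which are not independent replicates, were 0.986 to 0.992 within groups and 0.947 to 0.961 between them. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Nor do they say that the knockdown libraries were derived separately. In all results below, other differences between the cultures therefore cannot be told apart from an effect of the knockdown.

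Ppp4r3a was lower in the knockdown libraries, at 4.06 ± 1.47 CPM (SD, n = 3) against 15.6 ± 2.29 CPM in WT (SD, n = 3). The log2 fold change was -1.94 (SE 0.24, adjusted p = 8.22e-05 by edgeR's quasi-likelihood test), which leaves 26.1% of the WT level. Its counts were 48, 122 and 94 in knockdown A, B and C, and 335, 227 and 260 in WT A, B and C. The gene, ENSMUSG00000041846, lies on the minus strand of chromosome 12 from 101039409 to 101083702 in GRCm38. The FPKM values of the authors were 0.304 ± 0.106 and 1.19 ± 0.176 (SD, n = 3). Its paralogue Ppp4r3b, another regulatory subunit, fell by 0.74 on the log2 scale (SE 0.22, adjusted p = 0.0179). That call was lost without knockdown A (adjusted p = 0.0616), knockdown C (0.0726), WT A (0.0633) or WT C (0.0595), and with library totals in place of TMM (0.0819). Ppp4c, the catalytic subunit, had a log2 fold change of -0.18 (adjusted p = 0.102; 0.0438 without knockdown A). For Ppp4r2 the change was 0.46 (adjusted p = 0.121; 0.0191 without knockdown A) and for Ppp4r1 0.15 (adjusted p = 0.207; 0.0169 with library totals). Of 5 tested members of the protein phosphatase 4 list, 0 were higher and 2 lower, and the same numbers were found adjusted over the list alone (camera adjusted p = 0.425); 1 was higher without knockdown A, and 1 lower without knockdown C, WT A or WT C.

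Across the transcriptome, a set of genes nearly silent in WT was expressed in the knockdown, and 2 genes of the interferon response, Rtp4 and Irf7, were among the 10 largest falls. Mgst1, a microsomal glutathione transferase, reached 61.8 ± 4.20 CPM in the knockdown against 0.0793 ± 0.0913 CPM in WT (SD, n = 3), where its counts were 0, 3 and 1. Npas2, a circadian transcription factor, rose by 5.41 (SE 0.25) and Agt, which encodes angiotensinogen, rose by 5.19 (SE 0.17) on the log2 scale. Rtp4, an interferon-induced gene, fell by 5.25 on the log2 scale (SE 0.21), Irf7, a transcription factor of the interferon response, fell by 4.44 (SE 0.13), complement C3 fell by 4.45 (SE 0.17) and the acute-phase gene Saa3 fell by 4.01 (SE 0.15). Ush1c, a scaffold protein, fell by 4.62 on the log2 scale (SE 0.09), from 218 ± 12.9 to 8.84 ± 0.440 CPM (SD, n = 3).

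Of 12269 genes tested, 4918 were called at an adjusted p under 0.05 (40.1%), 2515 higher and 2403 lower in the knockdown. Among them 1139 changed by at least 2-fold, 629 higher and 510 lower. The groups did not overlap for 6250 genes (50.9%), against 10% expected by chance for 3 libraries against 3. Ddah1, which degrades asymmetric dimethylarginine, had 1 count over the WT libraries and 722 over the knockdown libraries, a ratio of 592 (95% counting interval 106 to 23404). The neuronal intermediate filament gene Ina had 2 and 692 counts, a ratio of 284 (95% counting interval 78.2 to 2346). Intervals and floors cover counting error only. The other genes among the 10 largest rises were Sbsn, Echdc2, Dok7, Ogdhl and Ttc9, with log2 fold changes of 3.99 to 4.19. The other genes among the 10 largest falls were Rbpms, Fam213a, Galnt12, Abcg2, a membrane exporter, and Dennd2d, with log2 fold changes of -4.15 to -3.95. Fam213a lies on chromosome 14 past 40 Mb, where the median gene had a log2 fold change of -0.41, Ogdhl on the same chromosome before 40 Mb, where it had -0.05, and Rtp4 on chromosome 16, where it had 0.38. The median log2 fold change over all genes was 0.01 with TMM scaling and 0.17 with library totals, a shift of 0.159, and the share of calls that were higher went from 51.1% (2515 of 4918) to 71.3% (3893 of 5461). Rises and falls printed with an SE are log2 fold changes on the TMM scale.

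**Figure D1:**
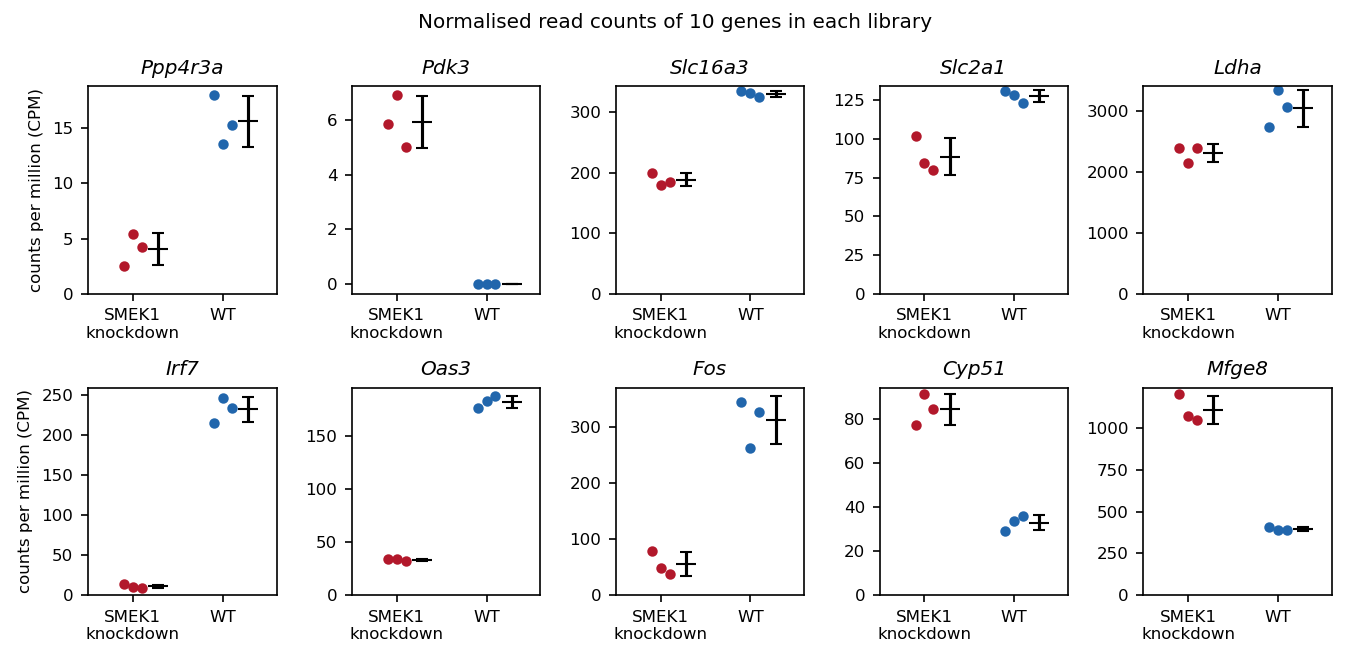
Normalised read counts (CPM, vertical axes starting at 0 or just below it) of 10 genes in the SMEK1 knockdown libraries (red) and the WT libraries (blue); each point is a library and black bars give the mean ± SD (n = 3). Ppp4r3a lies at 2.51 to 5.42 CPM in the knockdown and 13.5 to 18.1 CPM in WT, and Pdk3 has no count in any WT library.

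Among 56 gene lists written before the data were examined, 48 had at least 5 tested members, and camera called 12 of them, 4 higher and 8 lower in the knockdown. Splits of the libraries that mix the groups gave 2 to 9 list calls by the same test. The lists held 1032 tested genes, of which 552 were called (53.5%), 197 higher and 355 lower; with library totals 600 were called, 321 higher and 279 lower. When the correlation between genes was estimated from the residuals in place of the preset value, the call for the type I interferon response held and the other 11 did not, with 4 lists at an unadjusted p under 0.05.

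**Figure D2:**
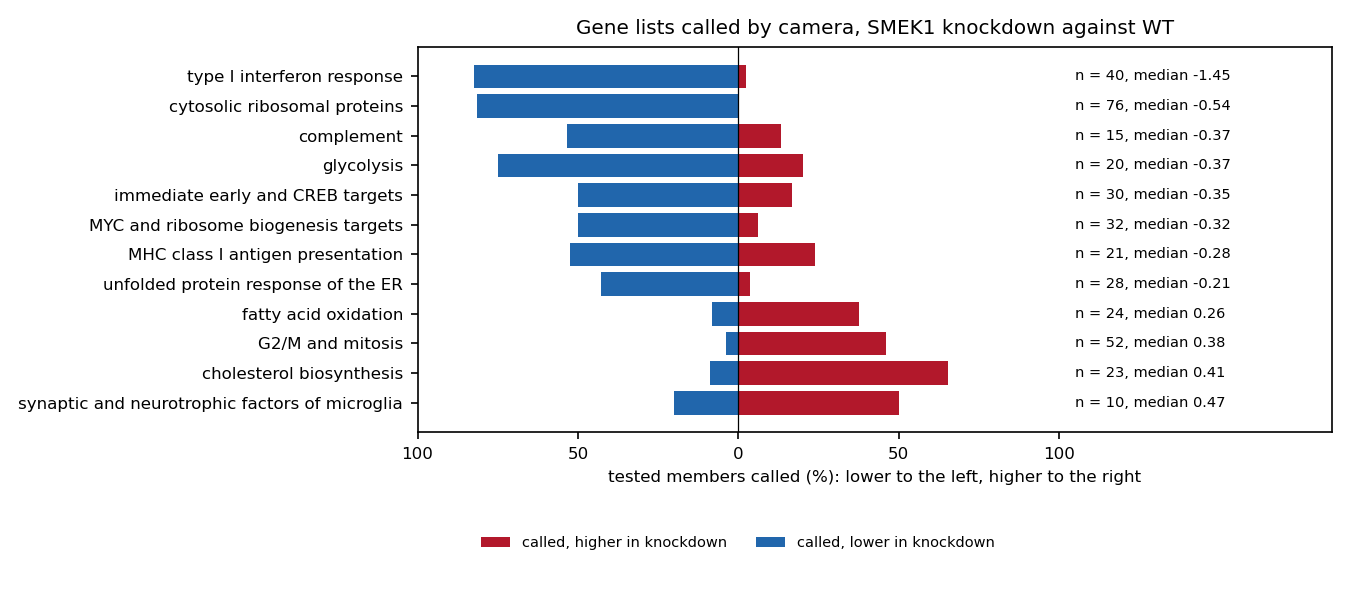
Percentage of tested members called higher (red, to the right) and lower (blue, to the left) in the SMEK1 knockdown for the 12 gene lists called by camera, with the number of tested members and the median log2 fold change beside each. The type I interferon list has the lowest median, -1.45, with 33 of 40 members lower.

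Type I interferon response genes fell together. Of 40 tested members 33 were lower and 1 higher, or 34 and 1 adjusted over the list alone, with a median log2 fold change of -1.45 (camera adjusted p = 1.93e-43; adjusted p = 0.00363 with an estimated correlation). Oas3, a sensor of double-stranded RNA, fell by 2.45 on the log2 scale (SE 0.08, adjusted p = 2.82e-09), to 33.4 ± 1.01 CPM (SD, n = 3). Usp18, which removes ISG15 from proteins, fell by 3.20 (SE 0.12) and Ifi27l2a fell by 2.99 (SE 0.10) on the log2 scale. The higher member was Ifitm3, a membrane protein that restricts virus entry, which rose by 0.62 (SE 0.09). Of the 7 tested interferon-gamma GTPases and targets, 4 were lower and 1 higher, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.205; 0.0465 without knockdown C). The GTPase Irgm1 fell by 1.76 on the log2 scale (SE 0.14), while Cd274, the ligand of PD-1, rose by 1.41 (SE 0.17). Among 21 genes of MHC class I antigen presentation 11 fell and 5 rose, and the same numbers were found adjusted over the list alone; 3 rose without WT C. The median was -0.28 (camera adjusted p = 0.00652, and 0.0981 with limma-voom; adjusted p = 0.594 with an estimated correlation). H2-T23, a non-classical class I molecule, fell by 2.61 (SE 0.11) and Psme1, a proteasome activator subunit on chromosome 14, fell by 1.15 (SE 0.09) on the log2 scale, while H2-Q4 rose by 1.15 (SE 0.15). The H2 heavy-chain genes of class I share much of their sequence, so counts of single members are uncertain. MHC class II had 2 lower and 1 higher of 9 members, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0612; 0.00197 without knockdown A, 0.0416 without knockdown C, 0.0126 at 1 count in any library, 0.0317 with the residual covariate and 0.049 with the replicate block).

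Complement genes were lower as a list: 8 of 15 fell and 2 rose, with the same numbers adjusted over the list alone and a median of -0.37 (camera adjusted p = 0.00958, and 0.0664 with limma-voom; adjusted p = 0.351 with an estimated correlation). Cfp, which encodes properdin, fell by 1.00 (SE 0.08) and C4b fell by 1.84 (SE 0.23) on the log2 scale, while the receptor gene C3ar1 rose by 0.74 (SE 0.09). Of 18 inflammatory cytokines and mediators 7 fell and 4 rose, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.0547; 0.0465 without knockdown C, 0.0484 without WT B, 0.035 with library totals, 0.0323 at 1 CPM in 3 libraries and 0.021 at 1 count in any library). The 4 rising members numbered 2 without knockdown C, WT B or WT C. Acod1, which makes itaconate and lies on chromosome 14, fell by 2.76 (SE 0.21) and Nlrp3, an inflammasome sensor, fell by 0.87 (SE 0.12) on the log2 scale, while Hmgb1, a nuclear protein that acts as a danger signal outside cells, rose by 0.77 (SE 0.11). Tnf had a log2 fold change of -0.01 (SE 0.12, adjusted p = 0.938), with 16.5 ± 0.906 CPM in the knockdown and 16.6 ± 0.620 CPM in WT (SD, n = 3). Il1b, Il6 and Nos2 had too few counts to be tested, at 0.162, 0.0148 and 0.0998 CPM in the knockdown and 0.349, 0.0559 and 0.193 CPM in WT. Ptgs2, the inducible cyclooxygenase, fell by 0.95 on the log2 scale (SE 0.27, adjusted p = 0.0159), a call lost without knockdown C (0.0732) or WT A (0.0807). Of 13 chemokines and their receptors 6 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.511). Ccl2, a monocyte attractant, fell by 1.27 (SE 0.10) on the log2 scale and Cxcr4, the receptor of CXCL12, rose by 2.48 (SE 0.10).

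Of 22 NF-kappaB feedback and target genes 8 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.183), and with library totals 7 fell and 6 rose; 1 rose without WT C. Nfkbia, the inhibitor of NF-kappaB, fell by 1.36 (SE 0.11) and Nfkb2 fell by 0.75 (SE 0.09) on the log2 scale, while the dendritic cell marker Cd83 rose by 0.91 (SE 0.11). Toll-like receptor signalling had 7 lower and 3 higher of 21 genes, the same adjusted over the list alone (camera adjusted p = 0.287), and the receptor gene Tlr2 fell by 0.99 (SE 0.09) on the log2 scale. Of 16 pyroptosis and inflammasome genes 4 rose and 4 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.474); 2 rose without knockdown B, knockdown C or WT B, and 1 without WT C. P2rx7, an ATP-gated channel, rose by 0.64 (SE 0.08).

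Of 20 tested glycolysis genes 15 fell and 4 rose, with the same numbers adjusted over the list alone and a median of -0.37 (camera adjusted p = 0.00339; adjusted p = 0.594 with an estimated correlation). Pdk3, a pyruvate dehydrogenase kinase gene on the X chromosome from 93764607 to 93832201, had 112, 155 and 111 counts in knockdown A, B and C and 0 in each WT library, at least 103-fold higher against a floor of 3 counts over the group (adjusted p = 1.78e-06). Pdk1 fell by 0.33 on the log2 scale (SE 0.08, adjusted p = 0.00544), a call lost with library totals (adjusted p = 0.103). Pdk2 and Pdk4 had 0 counts in every library, which allows up to 3 counts over each group, 0.0470 CPM in the knockdown and 0.0574 CPM in WT. Pdha1, a subunit of pyruvate dehydrogenase itself, had a log2 fold change of 0.05 (SE 0.08, adjusted p = 0.665). Of the 10 tested genes of pyruvate dehydrogenase and its kinases 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.425); 2 rose without knockdown B. Lower glycolysis members numbered 8 without knockdown C, and higher members 2 without knockdown A or WT B. The muscle-type enolase gene Eno3 fell by 0.97 (SE 0.08), the phosphofructokinase gene Pfkl fell by 1.08 (SE 0.10) and Gpi1, glucose-6-phosphate isomerase, fell by 0.71 (SE 0.08) on the log2 scale. Glucose transporter Slc2a1 fell by 0.53 (SE 0.10) and hexokinase Hk2 fell by 0.47 (SE 0.09) on the log2 scale, while Pfkfb3, which makes the activator of phosphofructokinase, rose by 0.76 (SE 0.13). Pkm, the pyruvate kinase gene, had -0.12 (SE 0.09, adjusted p = 0.318). Gapdh was called higher, but its counts were 329, 10339 and 8926 in knockdown A, B and C and 743, 311 and 273 in WT A, B and C. It has near-identical pseudogene copies, and limma-voom did not call it (adjusted p = 0.0894). Without Gapdh the other 19 glycolysis genes had a median log2 fold change of -0.40 and a mean of -0.35.

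Lactate dehydrogenase Ldha fell by 0.40 on the log2 scale (SE 0.10, adjusted p = 0.00684), from 3053 ± 304 to 2311 ± 143 CPM (SD, n = 3). The lactate exporter gene Slc16a3 fell by 0.81 on the log2 scale (SE 0.08, adjusted p = 9.25e-06), from 331 ± 5.10 to 188 ± 10.5 CPM (SD, n = 3). Slc16a1, another monocarboxylate transporter, had -0.07 (SE 0.09, adjusted p = 0.573), and Ldhb had 0 counts in every library. Of 11 tested genes of lactate production and transport 4 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.508); 1 rose without knockdown C or WT A. Acss2, which makes acetyl-CoA from acetate, rose by 1.15 (SE 0.23). Enzymes proposed to write or erase histone acylation were mostly not called: 3 of 20 were higher and 1 lower, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.76), and 5 were higher without WT A; 2 were lower without knockdown B or WT B and 0 without knockdown C or WT C. This list had a median of -0.03 and a mean of 0.03, and the camera direction was up. The acetyltransferase gene Ep300 had a log2 fold change of -0.31 (SE 0.17, adjusted p = 0.155; 0.0476 without knockdown B and 0.0451 without WT B). The deacetylase gene Hdac1 had -0.18 (adjusted p = 0.102; 0.0384 without WT A), Hdac2 had 0.44 (adjusted p = 0.0882; 0.00736 without knockdown A and 0.0441 without WT A) and Hdac3 had 0.03 (adjusted p = 0.803; 0.0362 with library totals). Of 17 tested enzymes of histone H3 lysine 9 methylation 4 were lower and 0 higher, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.287); 2 were lower without knockdown C or WT C.

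Of 22 tricarboxylic acid cycle genes 7 rose and 4 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.643); 4 rose without knockdown C, and 12 with library totals. Idh2, mitochondrial isocitrate dehydrogenase, rose by 0.71 (SE 0.09), while Ogdh and Dlst, subunits of the oxoglutarate dehydrogenase complex, fell by 0.62 (SE 0.08) and fell by 0.69 (SE 0.09) on the log2 scale, respectively. Respiratory chain genes of the nucleus went both ways, with 12 of 49 lower and 8 higher, the same adjusted over the list alone (camera adjusted p = 0.835); the median was 0.01 and the mean -0.02, with the camera direction down. With library totals 9 were lower and 25 higher. The pentose phosphate pathway had 5 of 9 genes lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.205); 3 were lower without knockdown B, knockdown C or WT C, and 1 higher without knockdown B or WT B. Pgd, which makes NADPH, fell by 0.71 (SE 0.10) on the log2 scale. Of 26 tested hypoxia-inducible factor targets 9 fell and 4 rose, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.335), and 7 rose with library totals. Ddit4, an inhibitor of mTORC1, fell by 1.41 (SE 0.10) and the prolyl hydroxylase gene Egln3 fell by 2.10 (SE 0.29) on the log2 scale. Hif1a itself had -0.09 (SE 0.22, adjusted p = 0.762).

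Ribosomal protein mRNAs were lower as a group: 62 of 76 cytosolic ribosomal protein genes fell and 0 rose, or 69 fell and 1 rose adjusted over the list alone. Their median log2 fold change was -0.54 with TMM and -0.38 with library totals (camera adjusted p = 2.33e-17; adjusted p = 0.594 with an estimated correlation). Together they took 14.3% ± 0.579 of all counts in the knockdown and 18.8% ± 0.685 in WT (SD, n = 3; exact two-sided permutation p = 0.1, the smallest this design allows). Rpl13a fell by 1.03 (SE 0.09) and Fau fell by 0.83 (SE 0.09) on the log2 scale. Many of these genes have processed pseudogenes, so single values are uncertain. Of 32 MYC and ribosome biogenesis targets 16 fell and 2 rose, with the same numbers adjusted over the list alone and a median of -0.32 (camera adjusted p = 0.00778; adjusted p = 0.351 with an estimated correlation). With library totals 10 fell and 5 rose; without knockdown C, WT A or WT C 1 rose. Bop1, needed for large ribosomal subunit assembly, fell by 0.72 (SE 0.07) and spermidine synthase Srm fell by 0.70 (SE 0.08) on the log2 scale, while Myc itself rose by 1.35 (SE 0.33).

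Immediate early genes fell, 15 of 30 with 5 higher, or 15 and 6 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.00115; adjusted p = 0.594 with an estimated correlation); 3 were higher without WT C. Fos fell from 311 ± 42.6 to 54.4 ± 21.4 CPM (SD, n = 3; log2 fold change -2.52, SE 0.22), Fosb fell by 3.04 (SE 0.22) and Ier3, a stress-induced survival gene, fell by 2.49 (SE 0.13) on the log2 scale. Atf3, a stress-induced transcription factor, rose by 1.19 (SE 0.09). Of 28 genes of the unfolded protein response 12 fell and 1 rose, with the same numbers adjusted over the list alone and a median of -0.21 (camera adjusted p = 0.00958; adjusted p = 0.594 with an estimated correlation); 2 rose without knockdown B and 0 without WT B or WT C. Xbp1, a transcription factor of this response, fell by 1.16 (SE 0.12) and Derl1, which acts in the removal of misfolded proteins, fell by 0.87 (SE 0.10) on the log2 scale. The integrated stress response was divided, with 9 of 29 genes lower and 8 higher, the same adjusted over the list alone (camera adjusted p = 0.616), and 14 higher with library totals. Ddit3, which encodes CHOP, rose by 1.64 (SE 0.09), while asparagine synthetase Asns fell by 0.80 (SE 0.10) on the log2 scale. Heat shock genes had 5 of 16 lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.202); 3 were lower without knockdown C or WT C, and 8 were lower and 1 higher without WT A. The chaperone gene Hspa8 fell by 0.70 (SE 0.09) on the log2 scale. Of 25 NRF2 antioxidant targets 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.511); 7 fell without knockdown C or WT C, and 5 fell and 7 rose with library totals. Srxn1, which repairs oxidised peroxiredoxins, rose by 1.04 (SE 0.10).

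Genes of G2/M and mitosis rose, 24 of 52 with 2 lower, or 26 and 2 adjusted over the list alone. The median was 0.38 (camera adjusted p = 0.00192, adjusted p = 0.643 with an estimated correlation and 0.0596 with fry). The mitotic kinase Aurka rose by 0.94 (SE 0.09), Racgap1, which acts in cytokinesis, rose by 0.90 (SE 0.09) and cyclin Ccnb2 rose by 0.85 (SE 0.11), while the phosphatase gene Cdc25b fell by 0.49 (SE 0.07) on the log2 scale. Of 47 G1/S and DNA replication genes 17 fell and 7 rose, or 17 and 8 adjusted over the list alone (camera adjusted p = 0.25). Here 11 fell without WT C, and 11 fell and 14 rose with library totals, where the list median changed sign. The replicative helicase subunit Mcm5 fell by 0.60 (SE 0.08) and Cdca7 fell by 1.20 (SE 0.09) on the log2 scale, while Gins1, part of the same helicase complex, rose by 0.73 (SE 0.13). Of 22 p53 targets 8 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.205), and 5 rose without WT C. Plk2 rose by 0.98 (SE 0.12) and the nuclease gene Aen rose by 0.83 (SE 0.11), while Btg2 fell by 3.14 (SE 0.36) on the log2 scale. DNA damage response genes had 4 of 34 lower and 3 higher, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.88); 1 was lower without knockdown A, knockdown C, WT A or WT C, and 5 were higher without knockdown A. Apoptosis genes had 5 of 27 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.643); 6 were higher without knockdown B, 3 lower without WT A, and 2 lower and 12 higher with library totals.

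Cholesterol biosynthesis genes rose, 15 of 23 with 2 lower, or 17 and 2 adjusted over the list alone, with a median of 0.41 (camera adjusted p = 8.08e-05; adjusted p = 0.351 with an estimated correlation); 1 was lower without knockdown B, knockdown C, WT B or WT C. Cyp51, lanosterol demethylase, rose by 1.36 (SE 0.10), from 32.9 ± 3.39 to 84.3 ± 6.89 CPM (SD, n = 3), Mvk, mevalonate kinase, rose by 1.11 (SE 0.09) and Hsd17b7 rose by 1.71 (SE 0.15). Of 24 fatty acid oxidation genes 9 rose and 2 fell, with the same numbers adjusted over the list alone and a median of 0.26 (camera adjusted p = 0.0254, and 0.0572 without WT A; adjusted p = 0.594 with an estimated correlation). With library totals 15 rose, and 1 fell without knockdown B, WT B or WT C. Acadl, long-chain acyl-CoA dehydrogenase, rose by 1.84 (SE 0.13), and the lipid droplet protein gene Plin2 rose by 1.22 (SE 0.11). Fatty acid synthesis had 4 of 17 genes lower and 1 higher, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.335), and 2 lower without knockdown C or WT C. LXR targets had 4 of 11 lower and 2 higher, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.646); 2 were lower without knockdown B, knockdown C, WT B or WT C, and 1 was higher without WT B and 0 without WT C. The cholesterol exporter gene Abcg1 fell by 0.38 (SE 0.08) on the log2 scale. Lysosomal genes had 18 of 42 higher and 6 lower, or 20 and 6 adjusted over the list alone (camera adjusted p = 0.0501; 0.0141 without knockdown B, 0.0175 without knockdown C and 0.0484 without WT B). This list was also called with library totals (0.0042), limma-voom (0.0343), either other filter on low counts (0.0455 at 1 CPM in 3 libraries, 0.00234 at 1 count), the residual covariate (0.0317) and without chromosomes 14 and 16 (0.0411). The lower members numbered 3 without knockdown B, 2 without knockdown C and 3 without WT C. Cathepsin Ctsh rose by 1.73 (SE 0.08) and cathepsin Ctsf fell by 1.41 (SE 0.08) on the log2 scale. Of 26 autophagy genes 6 rose and 3 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.508), and 13 rose with library totals; Gabarapl1, an autophagosome protein, rose by 0.62 (SE 0.11). Ferroptosis and iron handling had 7 of 19 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.335), and the iron exporter gene Slc40a1 fell by 0.90 (SE 0.14) on the log2 scale.

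Genes that mark microglial states went both ways. Of 17 homeostatic microglia genes 8 rose and 6 fell, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.462); 3 fell without knockdown C and with library totals. Tmem119 rose by 1.00 (SE 0.14), while the CSF1 receptor gene Csf1r fell by 0.73 (SE 0.07) on the log2 scale. Among 29 disease-associated microglia genes 10 fell and 9 rose, the same adjusted over the list alone (camera adjusted p = 0.694). Lysozyme Lyz2 fell by 1.14 (SE 0.13) on the log2 scale, and Igf1, a growth factor, rose by 1.15 (SE 0.10). Alternative activation genes had 6 of 16 lower and 4 higher, the same adjusted over the list alone (camera adjusted p = 0.903). Arg1, arginase, rose by 3.45 (SE 0.44) to 4.08 ± 1.75 CPM from 0.370 ± 0.180 CPM (SD, n = 3), and Il4ra, the interleukin receptor subunit, fell by 0.96 (SE 0.12) on the log2 scale. Of 25 phagocytic receptors and their partners 9 fell and 7 rose, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.425); 4 fell without knockdown C or WT C, and 3 with library totals. Mfge8, which bridges dying cells to phagocytes, rose from 398 ± 11.7 to 1110 ± 83.2 CPM (SD, n = 3; log2 fold change 1.48, SE 0.09), and the Fc receptor gene Fcgr4 fell by 0.94 (SE 0.12) on the log2 scale. The synaptic and neurotrophic list was called higher, with 5 of 10 rising and 2 falling, the same adjusted over the list alone, and a median of 0.47 (camera adjusted p = 0.0254, 0.0538 without WT B and 0.187 with limma-voom; adjusted p = 0.594 with an estimated correlation). No member fell without knockdown C or WT C. Its risen members include Mfge8, Igf1 and the vascular growth factor genes Pdgfb, 1.03 (SE 0.16), and Vegfa, 0.53 (SE 0.09). Macrophage migration and adhesion had 10 of 28 lower and 6 higher, the same adjusted over the list alone (camera adjusted p = 0.88), and 10 higher with library totals; Fscn1, an actin-bundling protein gene, rose by 3.32 (SE 0.33). TGF-beta response genes had 4 of 16 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.425), and Id3 fell by 1.00 (SE 0.12) on the log2 scale. Of 13 extracellular matrix genes 6 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.46), and the basement membrane collagen gene Col4a1 rose by 1.95 (SE 0.15).

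Most markers of other cell types lay below 1 CPM in both groups. No epithelial or lymphocyte marker reached 1 CPM in either group, of 10 and 13 listed, and of 16 neuron markers 2 did in the knockdown and 1 in WT. Single members of the remaining lists were expressed, such as Vim at 1743 CPM in the knockdown and 1148 CPM in WT among 14 fibroblast markers, 3 of which reached 1 CPM in each group. Of 11 astrocyte markers 1 did in each group, Aldoc, and of 10 endothelial markers 2 did in each. Oligodendrocyte lineage markers above 1 CPM numbered 3 of 12 in the knockdown and 2 in WT, and neutrophil and mast cell markers 0 of 12 and 1. Mitochondrial transcripts took 0.658% ± 0.155 of counts in the knockdown and 0.723% ± 0.107 in WT (SD, n = 3; exact two-sided permutation p = 0.7). Of 11 tested mitochondrially encoded mRNAs 1 was lower and 0 higher, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.474); 2 were lower without knockdown B or WT B and 0 without knockdown A or WT A.

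Fold changes also differed by chromosome, a comparison chosen after the values were seen. Among 9493 genes with a mean log2 CPM above 2, the 305 genes of chromosome 16 had a median log2 fold change of 0.38, and 161 were called higher and 19 lower. The 318 genes of chromosome 14 had a median of -0.33, with 149 called lower and 23 higher. Past 40 Mb, a cut placed after the values were seen, the median of chromosome 14 was -0.41 (225 genes), against -0.05 for the 93 genes before it. From 90 to 120 Mb, a part picked by its values where Acod1 also lies, all 25 genes lay below 0, with a median of -0.98. The other autosomes and the X chromosome had medians between -0.15 (chromosome 19) and 0.15 (chromosome 2). Parts of them, picked by their values, were shifted as well. Medians were 0.33 on chromosome 2 past 140 Mb (237 genes) and 0.39 on chromosome 18 past 60 Mb (95 genes). On chromosome 5 from 110 to 150 Mb the median was 0.23 (339 genes, leaving out 5 genes past 150 Mb with a median of -0.32). On chromosome 15 from 40 to 70 Mb it was -0.47 (42 genes). Genes named above that lie in these parts and moved the same way include Aurka, Gins1, Acss2, Srxn1, Tmem119, Mvk, P2rx7, Hmgb1 and Derl1. Oas3, Csf1r and Myc lie in them and moved the other way. The setting without chromosomes 14 and 16 kept these parts.

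**Figure D3:**
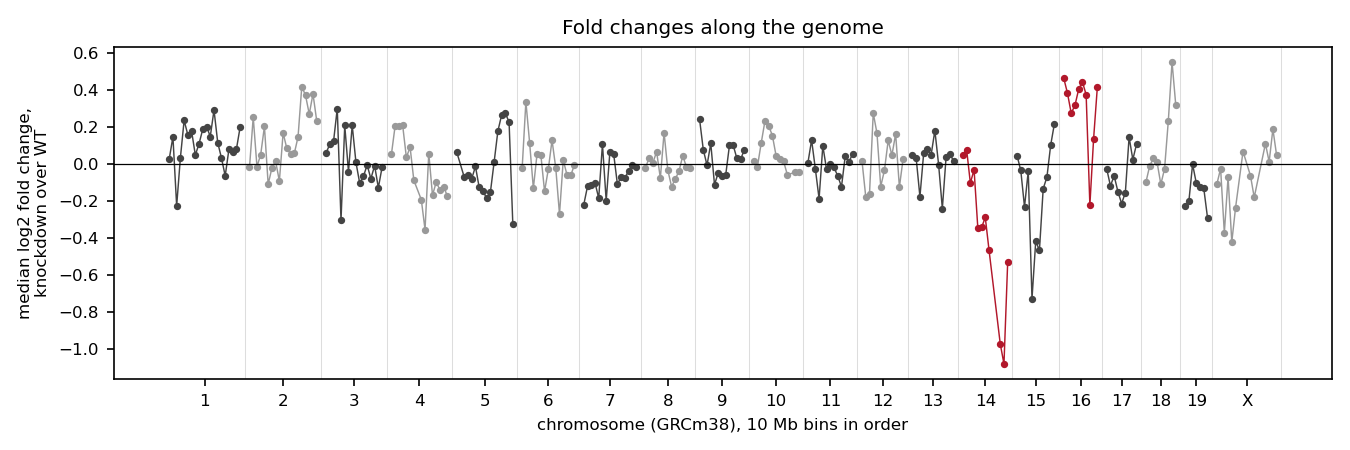
Median log2 fold change, knockdown over WT (vertical axis), in bins of 10 Mb with at least 5 genes, in order along the chromosomes of GRCm38 (horizontal axis); chromosomes 14 and 16 are red and the others alternate in grey. Most bins of chromosome 16 lie above 0, around its median of 0.38, and those of chromosome 14 past 40 Mb lie below 0.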

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

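The tests with a covariate from the residuals and without chromosomes 14 and 16 were chosen after the results were seen; all other settings were planned. The 4918 changed genes became 989 (514 higher, 475 lower) when tested against a fold of 1.5 and 3181 (1582 higher, 1599 lower) at an adjusted p under 0.01, both stricter by construction. The 12 shifted lists became 1 with an estimated correlation, and 31 (10 up, 21 down) with fry, which does not compare a list with other genes. The call for G2/M and mitosis was lost with fry (fry adjusted p = 0.0596). Other settings kept the counts of genes, list members and lists within 1.5 times. For the lists no result is given with upper quartile scaling, with DESeq2 in place of edgeR or with either FPKM scale. Leaving out 1 library gave 3703 (without knockdown C) to 4870 genes, 449 (without WT C) to 567 list members against 552, and 11 to 16 lists. Ppp4r3a ranged from -2.18 to -1.69 with a library left out, and was -0.74 on the log2(FPKM + 1) scale, which compresses low values. It kept its call in all 19 alternatives that were run for single genes (adjusted p = 2.03e-20 to 0.0028). These leave out the test against a fold of 1.5 and the adjusted p under 0.01, which were applied to the gene count alone. With the residual covariate 6871 genes were called. This covariate is built from the spread within the groups and removes part of it, so more calls could be expected from its making. The list calls with it carry the same limit. Without chromosomes 14 and 16 the count was 4515.

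Of 257 tested named genes 245 were called. Over the same 19 alternatives 210 of these kept their call wherever they were tested, 35 lost it in at least 1, and 0 reversed. Genes that a setting removed, by its filter or by chromosome, were not judged in that setting. The stricter fold and adjusted p settings were not applied to the named genes, so calls on small changes need not hold there. The letters A, B and C do not pair the libraries: residual correlations of same-letter libraries were -0.36, -0.33 and 0.00, and 0 of 6 libraries correlated best with their own letter. With the letter as a replicate block 3326 genes were called (3324 of them shared), 421 list members and 13 lists, and Ppp4r3a had -1.98 (adjusted p = 0.00219). Depth limits genes near 1 count, which stood for 0.0444 to 0.0597 CPM. The simulated recovery of 1.5-fold changes was 44.8%, with far fewer genes changed than were called in the data.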

Other observations

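The tests on pseudogenes of ribosomal proteins, on scaling, on the Gapdh copies taken alone, on unstable genes without Gapdh, on the glycolytic enzymes as a group and on chromosomes were chosen after the results were seen; those on matched genes, the sum of Gapdh and its copies, all 8 unstable genes and other splits were not.

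A small set of genes was close to on or off. Chosen after their values were seen, 18 genes had at most 3 counts over the WT libraries and at least 1 CPM in the knockdown, 16 of them protein-coding, and 4 genes showed the reverse. Besides Pdk3, the protein-coding genes with 0 WT counts were the septin gene Sept3 (at least 55.5-fold higher), the planar polarity gene Vangl1 (at least 36.6-fold), the synaptotagmin gene Syt14 (at least 31.1-fold) and the calcium channel subunit gene Cacna2d1 (at least 30.6-fold), each against a floor of 3 counts over the group. Wasf1, an actin regulator, had 202 counts in the knockdown and 3 in WT, a ratio of 55.2 (95% counting interval 18.6 to 270). The reverse genes were the tetraspanin gene Tspan7 (1 count against 147), the kinase gene Brsk2 (1 against 123), Zfp979 (3 against 98) and Traf1, an adaptor of TNF receptors (2 against 54).

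Chromosome 16 was shifted, with a median log2 fold change of 0.38, and so was chromosome 14, at -0.33, mainly past 40 Mb (-0.41, against -0.05 before it); parts of chromosomes 2, 5, 15 and 18 were shifted too. Chance placement of single genes is argued against, since 10000 shuffles of fold changes over gene positions gave a permutation p of 1e-04, the smallest they can give. The largest chromosome median of any shuffle was 0.133 in size. These shuffles treat neighbouring genes as exchangeable. A bias by transcript length, GC content or abundance is argued against too. The smaller of the sizes of the medians of chromosomes 14 and 16 stayed at 0.326 after those trends were removed. A candidate explanation is a copy number that differs between the cultures, which would move most genes of a chromosome or segment: against the chromosomes other than 14 and 16, the 10% point of fold changes on chromosome 16 lay 0.337 higher, where the median lay 0.375 higher (95% bootstrap interval of their ratio over genes 71.5% to 136%), and the upper 10% point on chromosome 14 past 40 Mb shifted by -0.462, the median by -0.411 (87.9% to 137%). An effect of the SMEK1 knockdown itself cannot be told apart from this, since all 3 knockdown libraries carried the shift of chromosome 16 (lowest median 0.323, highest 0.420) and no label says that they were derived separately. The cut at 40 Mb on chromosome 14 was placed after the values were seen, and the bootstrap interval does not cover that choice.

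Ribosomal protein genes were lower as a group, with a median of -0.54, a list call lost when the correlation was estimated (adjusted p = 0.594 with an estimated correlation). A transfer of reads to their pseudogenes is argued against, since the summed CPM of the genes and 391 annotated pseudogenes still had a log2 ratio of -0.548. Over 4 scalings of the same counts the ribosomal median ran from -0.552 to -0.384, and the median of all genes from 0.000979 to 0.169. A scaling moves all genes of a library together, so it does not change the fall of ribosomal genes relative to the others. Whether their absolute level fell cannot be decided from these scalings, since all of them rest on the same counts. Open is a bias by transcript length, GC content or abundance, which cannot be told apart: 121 other genes matched on these had a median of -0.148, between the bounds set beforehand as fractions of the ribosomal value. The knockdown itself stays open as a biological explanation, and was not tested apart from the libraries.

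Gapdh differed 28.6-fold between libraries, from 16.1 CPM in WT C to 459 CPM in knockdown B, with knockdown A at 17.2 CPM; no biological explanation of a change in Gapdh alone was tested, since the labels name no difference between libraries of a group. A change of the glycolytic enzymes as a group is argued against, since the largest ratio between libraries among Eno1, Aldoa, Tpi1, Pgk1 and Pgam1 was 1.64. A move of counted reads between Gapdh and its 190 copies is argued against too. The copies alone summed to 142 to 162 CPM, a range of 4.60% of that of Gapdh. Reads left out of the counts, such as those that match several places, cannot be judged from these values, since the counting program is not given. The sum with Gapdh differed 3.71-fold, between the bounds of 2 and 5 set beforehand, and decides nothing, as the copies add a near-constant amount. It differed 3.57-fold with 266 copies at a minimum of 200 aligned bases, used first by mistake. An uneven count of reads from genes with processed pseudogenes is a candidate explanation: of 8 genes, Gapdh among them, with a mean of at least 200 counts that differed over 4-fold within a group, 75% are pseudogenes or have one, against 17.4% of the other abundant genes (Fisher's exact test, p = 0.00056; 87.5% against 20.7% at 200 aligned bases). The share was 5 of 6 genes against 17.1% (Fisher's exact test, p = 0.000765) without Gapdh, which prompted the test, and with the mean asked of the group that differs, which leaves out Mgst1, abundant in the knockdown alone.

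The 6 libraries can be split into groups of 3 in 10 ways. For the genes, 1 of the 10 splits, the real one, gave as many as 4918 calls, and the highest count of the others was 0 by edgeR, with 33 to 692 genes at an unadjusted p under 0.05. For the lists, 1 of the 10 gave as many as 12, and the highest of the others was 9. With so few splits no share under 0.05 can be reached. Every other split also puts libraries of both groups on each side, so the difference between the groups adds to the spread within each side. Their 0 gene calls could follow from that alone and do not show what chance would give.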
